A study of Mus musculus with 6 samples.

How the data were processed

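The values analysed were Affymetrix probe set intensities, 1 value per probe set and array, from 6 arrays of total RNA labelled with biotin. Per the submitters' processing notes, the authors used MAS5 in Affymetrix Expression Console. Versions are not given in the sources used here. MAS5 gives each probe set a linear intensity from the perfect-match and mismatch probes of one array, and the deposited intensity values had a 2%-trimmed mean of 500.0 on every array. That scaling sets the overall brightness of the arrays equal, so a change in total RNA per cell cannot be seen, and MAS5 handles each array alone, so weak probe sets are noisy. Detection calls were not used here. The values of all 6 arrays come from 1 table.

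Of 45037 probe sets other than controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Names were taken only from probe sets with 1 symbol, together with 13 control probe sets of 4 genes (Actb, Gapdh, Pcx and Tfrc), 34958 in all, and symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, where 34754 were found and 0 symbols changed. This gave 18194 genes, of which 9012 had 2 or more probe sets. The genome build behind the array design is not given in the sources used here, so no coordinates are printed, and the RefSeq table served for names and for which genes neighbour each other.

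The choices described in this paragraph and the next were made before the data were examined, with 2 exceptions. The adjustment over the list alone and the test on simulated data were not among the choices set beforehand. Signals were kept on the deposited scale, raised to a floor at the 40th percentile of non-control probe sets (median over the arrays, a signal of 63.2), and put on the log2 scale. Each gene was represented by the probe set with the highest mean log2 signal. A gene was measured in a depot when at least 1 of its 2 arrays was above the floor. With 1 array per depot and genotype there is no test within a depot. Genes are counted when KO and WT differ by at least 2-fold with the brighter array above the floor, and a fold against an array at or under the floor is given as "at least". The error between probe sets is the SD of the log2 differences of the probe sets of one gene around their mean, pooled over genes with 2 or more probe sets above the floor on both arrays.

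Over depots, limma (version 3.58.1, R 4.3.3) was fitted to the 6 arrays with depot and genotype as terms on the 13233 genes above the floor on at least 3 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Its contrasts were KO against WT, brown against the mean of the white depots, and subcutaneous against epididymal fat. The depots stand in for replicates, so its p-values measure how alike the differences of the 3 depots are and not the spread between mice. Tested on simulated data with the same genes and spread, the genotype contrast recovered 0% of 200 genes changed by 1 on the log2 scale and 91.5% of 200 genes changed by 2. For 32 gene lists fixed beforehand (metabolic pathways, cell types, neighbouring tissues and regulatory programmes), the median log2 difference was set against 10000 random lists of the same size matched on mean signal in 20 bins. A list stands apart when its median lies outside the central 95% of those, as a description of these arrays. Random lists draw unrelated genes while members of a real list can vary together, so this is no test of genotype. "Over the list alone" means Benjamini-Hochberg adjustment of the limma p-values among the members of 1 list. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

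Genes are named by a rule fixed beforehand. Per depot it takes the 10 largest increases and the 10 largest decreases among genes past 2-fold with a brighter array of at least 2 times the floor, probe sets that go the same way and a characterised gene. It also takes genes past 2-fold in all 3 depots, up to 4 members of each list per depot, the 5 genes with the largest fold per direction between depots, and Kdm4b, its relatives and a few adipose and sex-linked genes. Alternatives were quantile normalization, centring each array on its median, floors at the 20th and 60th percentiles, the mean of all probe sets of a gene, leaving out probe sets that can cross-hybridise, thresholds of 1.5-fold and 3-fold, the mean of a list, limma without floor, without filter or with an intensity trend, and leaving out arrays or depots. The median log2 difference of all measured genes lay between -0.028 and 0.036 under the deposited and both other scalings. Leaving out the skeletal muscle list, or the thermogenic genes that muscle also expresses, was chosen after seeing the data.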

Results

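Gene expression was measured in epididymal, subcutaneous and brown fat of male mice that were wild type (WT) or lacked Kdm4b throughout the body (KO). Kdm4b encodes a histone demethylase that removes methyl groups from histone H3. The comparison addressed which transcripts differ in fat depots of mice whose Kdm4b deficiency leads to obesity. The mice were 2 months old, were kept at room temperature on chow, and were fasted for 6 hours before sampling. Each depot and genotype was represented by 1 Affymetrix array, 6 arrays in all, and the labels do not say how many mice gave each sample or whether the depots came from the same mice. There was thus no replicate within a depot, and the number of arrays limits the precision of every value. Fold differences within a depot are described by size, without a p-value. The only error available within a depot was the disagreement between probe sets of one gene, an SD of 0.31 in epididymal, 0.32 in subcutaneous and 0.32 in brown fat on the log2 scale, which leaves out the spread between mice. Between 12639 and 13594 of 18194 genes lay above the signal floor on an array.

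Brown fat carried transcripts of brown adipocytes, and the white depots differed in lymphoid and mesothelial transcripts. Ucp1, the uncoupling protein of brown adipocytes, was 12.5-fold higher in brown fat than in the mean of the white depots (limma adjusted p = 0.000454, 2 against 4 arrays). Between the white depots, it was 2.75-fold lower in subcutaneous than in epididymal fat (limma adjusted p = 0.0411, 2 against 2 arrays). Its signals were 6648.8 and 4782.7 in epididymal WT and KO, and 2934.3 and 1427.8 in subcutaneous WT and KO. Kng1 was at least 56.3-fold, Slc27a2 45.2-fold, Elovl3 31.0-fold, Fabp3 29.1-fold and Acot11 27.2-fold higher in brown fat. Lep, which encodes the satiety hormone leptin, was 25.6-fold lower there, next to Heph at 21.4-fold, Ighm at 21.0-fold, and Serpina3n and Fgf13 at at least 40.7-fold and 28.4-fold. Between the white depots, subcutaneous fat held more of the lymphoid transcripts Ighv14-2 (23.0-fold), Ltb (22.4-fold), H2-Ob (21.9-fold) and Ms4a4b (19.6-fold), and more of the matrix metalloproteinase gene Mmp3 (25.6-fold). Epididymal fat held more of the mesothelial genes Upk3b (at least 56.9-fold), Msln (at least 16.0-fold), Lrrn4 (13.8-fold) and Nkain4 (at least 13.4-fold), and of Slpi (27.2-fold). In the limma fit of all 6 arrays, 2854 genes rose and 4109 fell in brown against white fat, and 513 rose and 154 fell in subcutaneous against epididymal fat. The share of higher genes among the brown-fat calls was 41.0% on the deposited scale, 48.2% after quantile normalization and 55.1% after median centring. For subcutaneous against epididymal fat it was 76.9%, 61.9% and 69.9%, and with either epididymal array left out no more than 72 higher and 13 lower genes were called.

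Kdm4b itself was lower in the KO array of every depot. Its signal went from 226.7 to 188.4 in epididymal fat (log2 difference -0.27), from 272.1 to 156.7 in subcutaneous fat (-0.80) and from 134.6 to 95.2 in brown fat (-0.50). The epididymal difference was within the SD between probe sets. Kdm4b had 1 probe set, and the labels do not say which exons were deleted, so a probe set outside the deleted part checks nothing. Among the related demethylase genes, Kdm4a differed by 0.18, 0.14 and -0.08 in the 3 depots, Kdm4c by -0.29, -0.35 and -0.56, and Kdm4d was at or under the floor on all 6 arrays. The Y-linked genes Eif2s3y, Uty and Kdm5d had signals between 436.1 and 3293.0 on every array, while Xist, transcribed from the inactive X chromosome of females, stayed between 62.0 and 111.7, so every array carried male RNA.

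**Figure D1:**
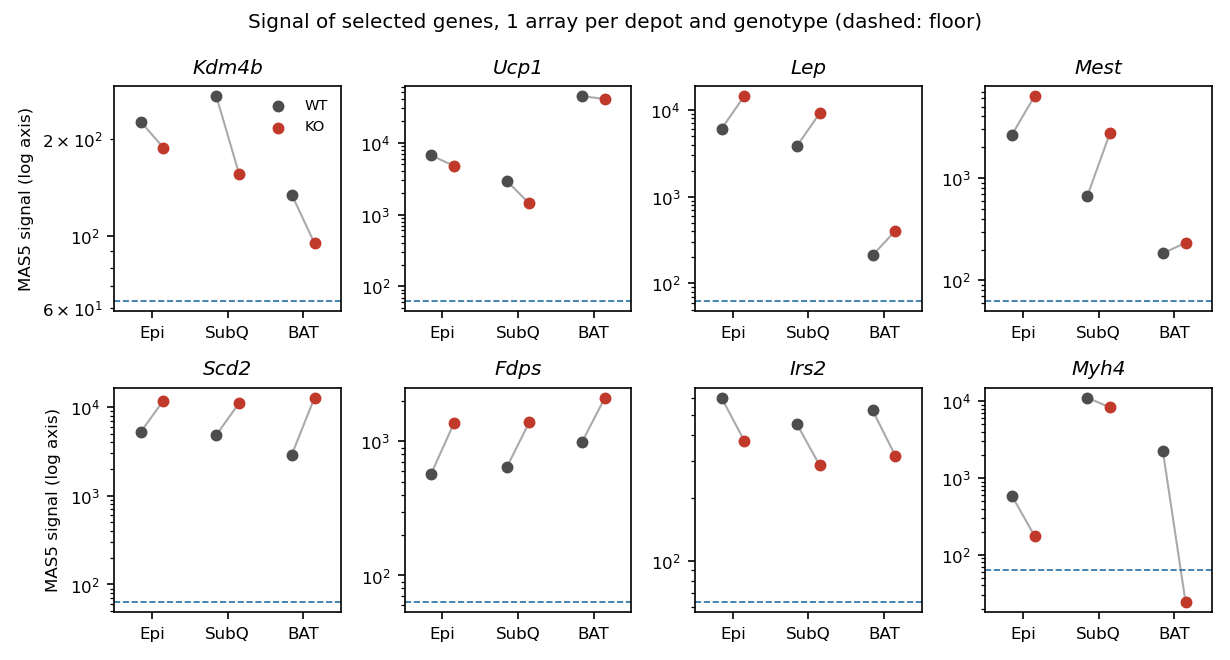
Signal of 8 genes on the 6 arrays, on a log axis that differs between panels; each point is 1 array, grey lines join WT (dark) and KO (red) of one depot, and the dashed line is the floor at a signal of 63.2. Kdm4b and Irs2 were lower and Lep, Scd2 and Fdps higher in the KO array of all 3 depots, and Myh4 in brown fat went from 2231.9 to 24.2.

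In epididymal fat, 115 genes were at least 2-fold higher and 186 at least 2-fold lower in the KO array, of 13225 measured. Rnase2a, a ribonuclease of the eosinophil family, had the largest increase, 25.9-fold, from a signal of 154.8 to 4016.2. Hspb7, a small heat shock protein gene, was 5.38-fold higher, Tph2 at least 5.19-fold, Plppr4 4.35-fold, Mogat2, a monoacylglycerol acyltransferase gene, 3.32-fold, and the cell cycle inhibitor gene Cdkn1a 3.24-fold. Akr1c12 (3.28-fold), Cyp2c23 (at least 3.14-fold), Pcolce2 (3.09-fold) and Ptx3 (3.05-fold) completed the 10 largest increases among the genes considered for naming. Among the decreases were the fast muscle myosin gene Myh1 (at least 8.80-fold), the antibody genes Igkv8-30 (7.35-fold), Jchain (4.35-fold) and Igkv14-111 (4.02-fold), and the cytochrome P450 gene Cyp2f2 (6.07-fold). Fbp1, a gluconeogenic enzyme gene, was at least 4.27-fold lower, as was Wdtc1. Skeletal muscle genes as a list were lower in the KO array, with a median of -0.94. Of the genes past 2-fold that had another probe set above the floor, 84.4% had it on the same side, against 63.0% of all measured genes. The share of higher genes among those past 2-fold was 38.2% on the deposited scale, 52.4% after quantile normalization and 48.8% after median centring.

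In subcutaneous fat, 305 genes were at least 2-fold higher and 100 at least 2-fold lower in the KO array, of 13857 measured. That KO array had the most genes above the floor of all arrays, 13594 against 12732 in subcutaneous WT. With the floor at the 60th percentile, 69 genes were higher and 47 lower. Muscle genes led the increases, with Myh1 21.2-fold, the myoglobin gene Mb 20.2-fold, Myh2 at least 12.4-fold, Mybpc1 7.97-fold, Myhas 6.00-fold and Lmod2 at least 5.08-fold higher. Hspb7 (at least 5.91-fold) and Rnase2a (at least 5.31-fold) were higher as in epididymal fat. Ncan (4.25-fold) and Krtap12-1 (at least 5.56-fold) were also higher, while Krtap12-1 was 3.67-fold lower in epididymal fat. Transcripts of the seminal vesicle led the decreases, with Svs2 6.76-fold, Svs4 5.26-fold and Svs5 5.07-fold lower. Glycam1, a mucin-like gene of lymph node vessels and mammary gland, was 3.85-fold lower, Cyp2f2 3.18-fold and Slc27a2, a fatty acid transporter gene, 3.16-fold lower. Gnal (4.07-fold), Pate14 (3.71-fold), Ceacam10 (3.58-fold) and Slit2 (at least 3.35-fold) were also lower. A second probe set lay on the same side for 67.5% of the genes past 2-fold, against 59.3% of all measured genes. The share of higher genes was 75.3% on the deposited scale, 64% after quantile normalization and 73.6% after median centring.

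In brown fat, 151 genes were at least 2-fold higher and 335 at least 2-fold lower in the KO array, of 13779 measured. The decreases were led by skeletal muscle genes, among them Myh4 (at least 35.3-fold), Tnnc2 (31.0-fold), Acta1 (27.7-fold), Tnni2 (at least 26.9-fold), Tnnt3 (at least 22.8-fold), Ckm (19.8-fold) and Myh1 (at least 17.2-fold). Nr4a3, an orphan nuclear receptor gene, was 13.0-fold lower. Without the muscle list, an alternative chosen after seeing the data, 311 genes were at least 2-fold lower. Scd2, a stearoyl-CoA desaturase gene, was 4.36-fold higher, from 2909.8 to 12693.0, and Fads3, a fatty acid desaturase family gene, 3.56-fold. Atp4b (at least 6.22-fold), Il17rc (at least 5.24-fold), Zdhhc12 (3.91-fold), Ttpa, which encodes a vitamin E transfer protein (3.67-fold), and Fer1l6 (3.34-fold) were also higher. Of the genes past 2-fold, 211 had the dimmer array at or under the floor, against 66 in epididymal and 123 in subcutaneous fat, so that their folds are lower bounds. A second probe set lay on the same side for 70.7% of the genes past 2-fold, against 60.3% of all measured genes. The share of higher genes was 31.1% on the deposited scale, 44.4% after quantile normalization and 33.6% after median centring.

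Genotype differences common to the 3 depots were few and included genes of lipid synthesis. Of 12157 genes measured in all 3 depots, 7 were at least 2-fold higher in each KO array and 0 were at least 2-fold lower in each. The numbers expected, if the depots were independent and all genes equally likely to differ, were 0.0194 and 0.0164. Fdps, a farnesyl diphosphate synthase gene of the mevalonate pathway, was higher by a mean log2 of 1.15 ± 0.08 (SD, n = 3 depots), and Scd2 was 2.82-fold higher on average, with an SD of 0.54 on the log2 scale. Fdps was not among the genes past 2-fold in all 3 depots after quantile normalization, nor with the mean of all probe sets, which gave log2 differences for Fdps of 0.62, 0.56 and 0.54. Tnfrsf12a, the receptor gene of the cytokine TWEAK, was higher by 1.36 ± 0.17, the natriuretic peptide gene Nppb by 1.41 ± 0.31, the proteoglycan gene Ncan by 1.55 ± 0.50 and Fbxw22 by 1.29 ± 0.08. For Nppb, Ncan and Fbxw22 the WT array lay at or under the floor in epididymal fat, and for Nppb also in subcutaneous fat, so these means are lower bounds. The last of the 7, Scyl2, at 1.16 ± 0.12, had probe sets that disagreed in direction and was named after its values were seen. Lep was higher by 1.25 in epididymal, 1.25 in subcutaneous and 0.94 in brown fat on the log2 scale. At 1.5-fold, 28 genes were higher and 36 lower in all 3 depots, against 1.61 and 1.97 expected. In the limma fit with depot as a block, 0 of 13233 genes passed for genotype at an adjusted p under 0.05 (smallest adjusted p = 0.439), with 501 higher and 601 lower at an unadjusted p under 0.05. With an intensity trend in the variance, 19 genes rose and 14 fell, among them Lep and Fdps, each higher in 3 of 3 depots (limma adjusted p = 0.015 for each). Across genes, which are not independent replicates, the KO over WT differences correlated between epididymal and subcutaneous fat with Pearson r = 0.26, between epididymal and brown fat with r = 0.12 and between subcutaneous and brown fat with r = 0.06. Spearman's rho was 0.26, 0.11 and 0.09 for the same pairs. Between subcutaneous and brown fat, 34 genes were at least 2-fold different in opposite directions, against 7.32 expected. Such genes numbered 12 against 3.91 expected between epididymal and subcutaneous fat, and 6 against 3.56 between epididymal and brown fat.

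**Figure D2:**
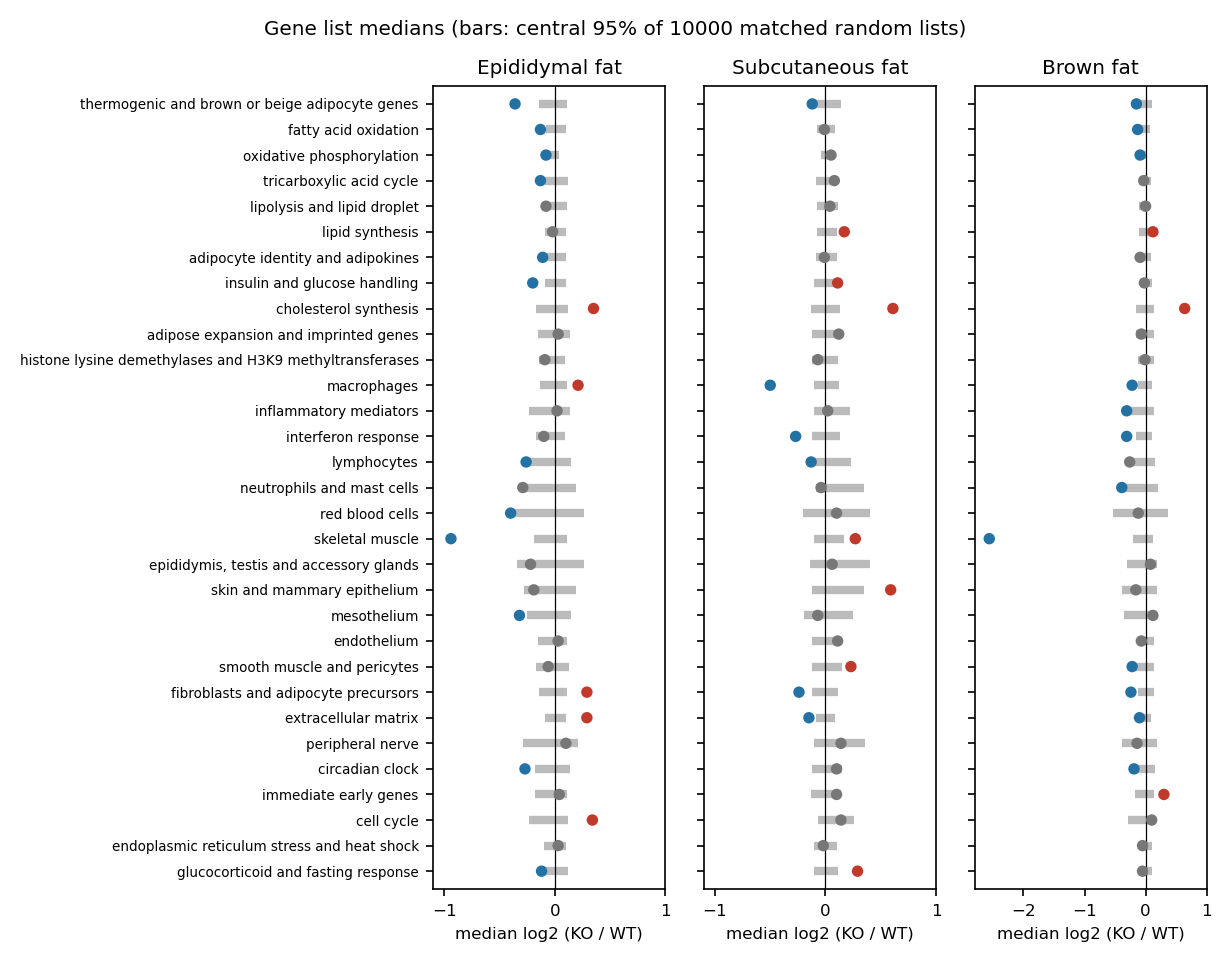
Median log2 KO over WT of 31 gene lists in each depot (points), with the central 95% of the medians of 10000 random lists matched on signal (grey bars); red and blue points lie above and below that range, and the axis of brown fat is wider than the others. The cholesterol synthesis median lies at 0.35, 0.61 and 0.64 in epididymal, subcutaneous and brown fat, and the skeletal muscle median at -0.94, 0.27 and -2.56.

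Cholesterol synthesis genes were higher in the KO array of all 3 depots. Of 21 members measured, 16 were higher in epididymal, 19 in subcutaneous and 18 in brown fat, with median log2 differences of 0.35, 0.61 and 0.64, and 0 of 10000 matched random lists reached these medians in any depot. Under alternative settings the lowest medians were 0.34, 0.42 and 0.38 in the same order, and each stayed above random lists in 6 of 6. Fdps was 2.38-fold, 2.18-fold and 2.13-fold higher in the 3 depots. Sqle, which encodes squalene epoxidase, was 2.28-fold higher in epididymal and 1.99-fold in subcutaneous fat, Lss, the lanosterol synthase gene, 2.52-fold in brown fat, and Nsdhl 2.06-fold in brown fat. Pmvk was 1.90-fold and Cyp51 1.72-fold higher in subcutaneous fat, and Insig1, a sterol sensor gene, 1.91-fold in brown fat. In the limma fit over depots, 11 of the 21 members rose when adjusted over the list alone (smallest adjusted p = 0.00317, Fdps, log2 difference 1.15 ± 0.11 SE, higher in 3 of 3 depots), and 0 over all genes tested. That adjustment does not cover the other lists tested in the same way.

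Lipid synthesis genes were higher in subcutaneous fat, where 19 of 27 were higher with a median of 0.17, and in brown fat, where 20 of 27 were higher with a median of 0.12. Both medians lay above the central 95% of random lists, and the epididymal median of -0.02 did not. Scd2 and Acss2, which makes acetyl-CoA from acetate, rose in the limma fit when adjusted over the list alone (adjusted p = 0.0295 and 0.0315), each higher in 3 of 3 depots, and 0 members passed over all genes. Elovl6, a fatty acid elongase gene, was 2.70-fold and Pnpla3 2.00-fold higher in subcutaneous fat, Me1 was 1.76-fold higher in brown fat, and Mogat2 was 3.32-fold and 2.16-fold higher in epididymal and subcutaneous fat. Acacb, an acetyl-CoA carboxylase gene, was 2.07-fold lower in epididymal fat.

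**Figure D3:**
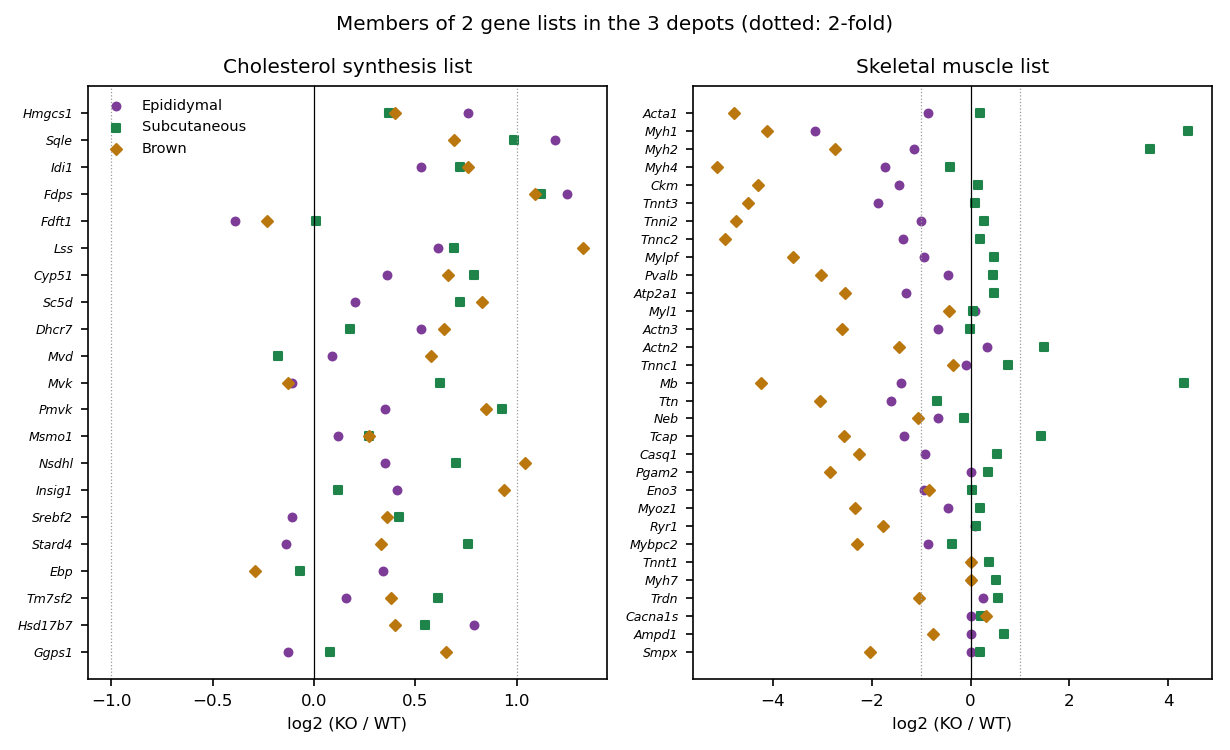
Log2 KO over WT of each member of the cholesterol synthesis list (left) and the skeletal muscle list (right) in epididymal (circles), subcutaneous (squares) and brown fat (diamonds); each point is 1 KO array over 1 WT array, and a point at 0 can be a gene at or under the floor on both. Cholesterol synthesis members lie mostly to the right of 0 in all depots, while the muscle genes lie to the left in brown fat, down to -5.14 or beyond for Myh4, and Myh1 and Mb lie at 4.41 and 4.33 in subcutaneous fat.

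Thermogenic and brown or beige adipocyte genes were lower in the KO arrays. In epididymal fat 19 of 24 measured members were lower (median -0.36), in subcutaneous fat 16 of 28 (-0.12) and in brown fat 20 of 26 (-0.15), and 0, 80 and 169 of 10000 random lists reached so low a median. Ucp1 was 1.39-fold lower in epididymal, 2.06-fold in subcutaneous and 1.09-fold in brown fat. Ppargc1a, a coactivator gene of mitochondrial biogenesis, was 1.71-fold lower in epididymal fat, and Pank1, of coenzyme A synthesis, 2.16-fold. In brown fat Dio2, the deiodinase gene that activates thyroid hormone, was 2.00-fold and Slc27a2 1.99-fold lower. Otop1 went the other way, 1.80-fold and 3.50-fold higher in epididymal and subcutaneous fat, as did Esrrg, at least 2.83-fold higher in subcutaneous fat. The list was mixed in that depot, where 12 of 28 members were higher, 2 of them at least 2-fold, and 4 were at least 2-fold lower. With the mean of all probe sets in place of the brightest, the subcutaneous median was -0.02, inside the range of random lists. The brown-fat median stayed below random lists under 4 of 6 alternative settings, and the epididymal one under 6 of 6. In the limma fit 0 members passed when adjusted over the list alone (smallest adjusted p = 0.0933) or over all genes. Skeletal muscle genes, with medians of -0.94, 0.27 and -2.56, moved the same way in epididymal and brown fat and the opposite way in subcutaneous fat.

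Fatty acid oxidation genes had medians of -0.13, -0.01 and -0.13 in epididymal, subcutaneous and brown fat, and those of epididymal and brown fat lay below random lists. Acot1 was 2.51-fold lower in epididymal and Ehhadh 2.22-fold lower in subcutaneous fat. Oxidative phosphorylation genes were lower for 51 of 70 members in epididymal fat (median -0.08) and 62 of 71 in brown fat (-0.09), both below random lists, with a median of 0.05 in subcutaneous fat. The brown-fat median of this list was up to -0.02 under alternative settings and stayed below random lists in 3 of 6, while the epididymal median for fatty acid oxidation stayed below in 5 of 6. By the mean of the list, the brown-fat value for fatty acid oxidation was -0.11, inside random lists. Tricarboxylic acid cycle genes had medians of -0.13, 0.08 and -0.03, of which the epididymal one lay below random lists. In these 3 lists 0 members passed in the limma fit, over the list alone or over all genes. The skeletal muscle list was lower in epididymal and brown fat too.

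Among adipocyte genes the hormone gene Lep stood out, 2.38-fold higher in epididymal fat (6063.3 to 14420.7), 2.38-fold in subcutaneous fat (3857.5 to 9177.6) and 1.92-fold in brown fat (210.7 to 404.1). It rose in the limma fit when adjusted over the list alone (adjusted p = 0.00775, higher in 3 of 3 depots). The list as a whole had medians of -0.11, -0.01 and -0.09, the epididymal one below random lists in the main analysis and in 5 of 6 alternative settings. By the mean of the list, epididymal fat had -0.03, inside random lists, and brown fat -0.14, below them. Adipoq, which encodes adiponectin, differed by -0.13, -0.04 and -0.25, and Pparg, the master regulator gene of adipocytes, by -0.21, -0.28 and -0.05. The Wnt inhibitor gene Sfrp5 was 2.91-fold and 2.56-fold higher in epididymal and subcutaneous fat and 1.92-fold lower in brown fat. Adipor2 was 1.67-fold and 1.43-fold lower in the white depots. In brown fat Klf15 was 2.08-fold and the resistin gene Retn 1.90-fold lower.

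The list of adipose expansion and imprinted genes had medians of 0.03, 0.12 and -0.07, none outside random lists, but by the mean of the list epididymal and subcutaneous fat had 0.19 and 0.30, above random lists. Mest, an imprinted gene whose expression goes with fat cell enlargement, was 2.39-fold higher in epididymal and 4.14-fold higher in subcutaneous fat, with a log2 difference of 0.34 in brown fat. Npr3, the clearance receptor gene of natriuretic peptides, was 2.17-fold and 2.14-fold higher in subcutaneous and brown fat and 1.40-fold in epididymal fat. Lipolysis and lipid droplet genes had medians of -0.08, 0.04 and 0.00, inside random lists in each depot, and means of -0.12 and 0.13 in epididymal and subcutaneous fat that lay outside. Fitm1, of lipid droplet formation, was 2.91-fold higher in subcutaneous fat. Insulin and glucose handling genes were lower for 24 of 31 members in epididymal fat (median -0.20) and higher for 19 of 31 in subcutaneous fat (0.11), both outside random lists, with -0.02 in brown fat. The subcutaneous median stayed outside in 5 of 6 alternative settings, and the mean there was 0.05, inside random lists. The skeletal muscle list, with medians of -0.94 and 0.27, moved the same way in these depots. Irs2, an insulin receptor substrate gene, was 1.60-fold, 1.57-fold and 1.65-fold lower in the 3 depots and fell in the limma fit when adjusted over the list alone (adjusted p = 0.0481, lower in 3 of 3 depots). Tbc1d4, which acts in glucose transporter traffic, was 1.84-fold and 1.79-fold lower in epididymal and brown fat, and Insr 1.61-fold lower in subcutaneous fat. Of these 3 lists and the adipocyte list, 0 members passed over all genes.

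Macrophage genes were higher in epididymal fat and lower in the other depots. In epididymal fat 24 of 28 members were higher (median 0.21), in subcutaneous fat 27 of 28 were lower (-0.50) and in brown fat 21 of 26 (-0.22), each outside random lists. Clec7a was 1.55-fold and Ccr2 1.43-fold higher in epididymal fat, but Gpnmb, the member with the largest difference there, was 1.57-fold lower. Fcgr1 was 2.12-fold and Lgmn 1.93-fold lower in subcutaneous fat, and Cd14 1.81-fold and Mrc1 1.72-fold lower in brown fat. Interferon response genes had medians of -0.10, -0.27 and -0.31, below random lists in subcutaneous and brown fat, where Oasl2 was 2.56-fold and Ifi27l2a 2.41-fold lower. The epididymal mean of that list was -0.21, below random lists. Inflammatory mediators had medians of 0.02, 0.02 and -0.31, the last below random lists in the main analysis and in 5 of 6 alternative settings. The chemokine genes Ccl2 and Ccl7 were 2.28-fold and 2.05-fold higher in epididymal fat. Il1rn was 2.25-fold lower in brown fat, and Saa3 2.29-fold higher in subcutaneous fat. Lymphocyte genes had medians of -0.26, -0.13 and -0.26, the first and second below random lists, with Fcmr 2.14-fold lower in epididymal fat. The epididymal lymphocyte median stayed below in 4 of 6 alternative settings and the subcutaneous one in 5 of 6, and the epididymal mean of -0.20 lay inside random lists.

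In the list of neutrophil and mast cell genes, Mcpt4, Mmp9, Cma1 and Cpa3 fell in the limma fit when adjusted over the list alone. Their adjusted p were 0.0116, 0.0192, 0.0244 and 0.0244, each was lower in 3 of 3 depots, and 0 passed over all genes. Mcpt4 was 1.83-fold lower in epididymal and at least 2.16-fold lower in brown fat, and the gelatinase gene Mmp9 1.78-fold and 2.75-fold. Hdc, the histamine-forming enzyme gene, was 3.15-fold lower in epididymal fat. The neutrophil genes S100a8 (2.60-fold and 2.52-fold in epididymal and subcutaneous fat) and Ngp (3.65-fold in subcutaneous fat) were higher. The list as a whole had medians of -0.29, -0.04 and -0.39, of which the brown-fat one lay below random lists in the main analysis and in 4 of 6 alternative settings.

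Fibroblast and adipocyte precursor genes were higher in epididymal fat and lower in the other depots, with medians of 0.29, -0.24 and -0.24, each outside random lists. Pcolce2 was 3.09-fold and Col14a1 1.98-fold higher in epididymal fat, Cd248 2.11-fold lower in subcutaneous fat, and Lum 3.15-fold and Fbln1 2.20-fold lower in brown fat. Extracellular matrix genes had medians of 0.29, -0.15 and -0.10, also outside random lists, with Col12a1 2.17-fold higher in epididymal fat and Postn and Timp1 2.03-fold lower in subcutaneous fat. The brown-fat matrix median stayed below random lists in 4 of 6 alternative settings. Mmp2, a matrix metalloproteinase gene, was lower in 3 of 3 depots, by 2.07-fold in brown and 1.68-fold in epididymal fat, and fell in the limma fit when adjusted over the list alone (adjusted p = 0.0237) but not over all genes (adjusted p = 0.439). Endothelial genes had medians of 0.03, 0.11 and -0.07, inside random lists. Smooth muscle and pericyte genes had medians of -0.06, 0.23 and -0.22, outside random lists in subcutaneous and brown fat, with Acta2 1.35-fold higher and 1.75-fold lower. The subcutaneous and brown-fat medians each stayed outside in 5 of 6 alternative settings, and the subcutaneous mean of 0.11 lay inside random lists. The skeletal muscle list moved the same way in both of those depots. Peripheral nerve genes had medians of 0.10, 0.14 and -0.14, inside random lists.

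Genes of tissues other than fat also differed. Of the skeletal muscle list, 28 of 29 measured members were lower in brown fat, 24 of them at least 2-fold. In epididymal fat 21 of 25 were lower, 11 of them at least 2-fold. In subcutaneous fat 26 of 31 were higher, but only 5 of them at least 2-fold. Ckm and Tnnt3 differed there by 0.16 and 0.10 on the log2 scale, and Myh4 and Ttn by -0.42 and -0.67. Acta1 had a signal of 12806.9 in subcutaneous WT and 14588.7 in subcutaneous KO, against 4420.3 and 159.6 in brown fat. Skin and mammary epithelium genes were higher in subcutaneous fat (median 0.59, 14 of 17 members), with -0.19 and -0.16 in epididymal and brown fat. The keratin genes Krt18 and Krt8 were 3.20-fold and at least 2.53-fold higher there, and the median stayed above random lists in 5 of 6 alternative settings. Genes of the epididymis, testis and accessory glands had medians of -0.22, 0.06 and 0.08, inside random lists, while the subcutaneous mean, which the seminal vesicle genes named above lowered, was -0.56, below random lists. The seminal vesicle gene Svs5 had a signal of 3044.2 in subcutaneous WT and 1721.7 in epididymal WT. How such transcripts came to be in the subcutaneous sample was not tested. Mesothelial genes had medians of -0.32, -0.07 and 0.12, the first below random lists. Red blood cell genes had medians of -0.40, 0.10 and -0.12 over 6, 7 and 5 members, the first below random lists. The epididymal medians of mesothelial and of red blood cell genes stayed below in 5 of 6 alternative settings.

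Clock genes were lower in epididymal fat (median -0.27, 15 of 19 members) and brown fat (-0.19, 13 of 18), both below random lists, with 0.10 in subcutaneous fat. By the mean, brown fat had -0.17, inside random lists. The skeletal muscle medians of -0.94, 0.27 and -2.56 had the same signs as those of the clock list. Usp2 was 2.28-fold, Per3 1.92-fold and Dbp 1.73-fold lower in epididymal fat, and Cry1 was 2.06-fold higher in subcutaneous fat. Immediate early genes were higher in brown fat for 16 of 22 members (median 0.30, above random lists), with Fos 2.93-fold, Egr1 2.73-fold and Dusp1 2.29-fold higher but Nr4a3, the largest difference, 13.0-fold lower, and had medians of 0.04 and 0.10 in epididymal and subcutaneous fat. Cell cycle genes were higher in epididymal fat for 25 of 30 members (median 0.34, above random lists), with Prc1 and Ube2c 2.17-fold and 2.16-fold higher and the replication gene Mcm2 5.17-fold lower. Their medians in subcutaneous and brown fat were 0.14 and 0.10, inside random lists, with a brown-fat mean of 0.12, above them. Glucocorticoid and fasting response genes had medians of -0.12, 0.29 and -0.05, the first below and the second above random lists, with Cdkn1a 2.40-fold and Fkbp5 1.78-fold higher in subcutaneous fat. The epididymal median of this list was up to -0.04 under alternative settings and stayed below random lists in 4 of 6, and the mean was -0.01, inside them. The skeletal muscle list was also lower in epididymal and higher in subcutaneous fat. Endoplasmic reticulum stress and heat shock genes had medians of 0.03, -0.02 and -0.05, and histone demethylase and methyltransferase genes -0.09, -0.07 and -0.01, all inside random lists. Over the 32 lists, 17 stood apart in epididymal, 13 in subcutaneous and 15 in brown fat, against 1.6 expected per depot if members of a list varied independently. Members of a list can vary together, so standing apart is common here and is no test of any 1 list. The sex-linked genes had medians of 0.05, -0.04 and -0.02, inside random lists. In every list without a limma call given above, 0 members passed, over the list alone or over all genes. The ratio of 3' over 5' signal of the Gapdh control, a ratio that rises when RNA is degraded, differed by -0.20, -0.22 and -0.17 on the log2 scale between KO and WT in the 3 depots, that of Pcx by -0.30, -0.30 and -0.56, and that of Actb by -0.50, -0.28 and 0.03.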

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

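The tests of muscle genes, of scaling and of RNA integrity below were chosen after the results were seen, while those of genes near Kdm4b, of clusters elsewhere and of other splits of the arrays were set before.

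Several gene lists differed between KO and WT in opposite directions in different depots, each outside random lists. With 1 array per depot and genotype, the difference was not tested in any of these cases. The values here are gaps between the KO over WT medians of a pair of depots, on the log2 scale, and not differences in expression between depots. For skeletal muscle genes the gap was -1.21 for epididymal minus subcutaneous fat and 2.83 for subcutaneous minus brown fat. For macrophage genes it was 0.71 for epididymal minus subcutaneous and 0.43 for epididymal minus brown fat. For fibroblast and adipocyte precursor genes both such gaps were 0.53, and for extracellular matrix genes they were 0.44 and 0.39. Smooth muscle and pericyte genes had a gap of 0.45 for subcutaneous minus brown fat. Insulin and glucose handling genes had a gap of -0.31, and glucocorticoid and fasting response genes one of -0.41, for epididymal minus subcutaneous fat. Some of these medians lay inside random lists under alternative settings, namely those of smooth muscle genes in both depots, extracellular matrix genes in brown fat, insulin genes in subcutaneous fat and glucocorticoid genes in epididymal fat.

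Among the genes named by the rule, those past 2-fold in opposite directions included several muscle genes, and the difference was not tested for any of them. Between epididymal and subcutaneous fat the log2 KO over WT values of Myh1, Mb and Myh2 were apart by -7.54, -5.74 and -4.79, lower bounds in size because an array lay at or under the floor. Between subcutaneous and brown fat Mb was apart by 8.58, and Myh1, Myh2, Mybpc1 and Myhas by at least 8.51, 6.37, 5.29 and 4.14. The hair keratin-associated gene Krtap12-1 was apart by -4.35, also a lower bound in size, between epididymal and subcutaneous fat. Between epididymal and brown fat, the antibody genes Igkv8-30 and Jchain were apart by -3.88 and -3.41 and the seminal vesicle gene Svs2 by -2.29, and Svs2 was apart by -3.93 between subcutaneous and brown fat.

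Skeletal muscle genes were lower in the KO arrays of brown and epididymal fat and, by their median, higher in that of subcutaneous fat. In subcutaneous fat 26 of 31 members were higher, but only 5 at least 2-fold, among them Myh1 and Mb. Acta1, Ckm, Tnnt3 and Tnnc2 differed there by 0.19, 0.16, 0.10 and 0.19 on the log2 scale, and Myh4 and Ttn by -0.42 and -0.67. A genotype effect on muscle genes shared by the depots would lower them in subcutaneous fat too, where the median was 0.27, above random lists. With 1 array of each genotype in that depot, and muscle genes there as high as 12806.9 for Acta1 in WT, a different amount of muscle would hide such an effect, so the effect cannot be told apart from such differences. Muscle tissue in the WT samples of brown and epididymal fat, in amounts that differ between samples, stays open as well: 28 of 29 list members were lower in brown fat, but that share is the pattern itself and no separate test of it was run. A genotype effect that differs between depots was not tested.

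Cholesterol synthesis genes were higher in the KO arrays of all 3 depots. Scaling between the arrays is argued against, because the lowest median over the depots under quantile normalization and median centring was 0.34, with all medians still above random lists. Different amounts of skeletal muscle were predicted to turn the sign between subcutaneous fat and the other depots, and the lowest median as deposited was 0.35. That value is the pattern itself. Muscle genes such as Acta1 and Ckm also differed little in subcutaneous fat (0.19 and 0.16 on the log2 scale), so a turn of sign need not follow. The amount of muscle therefore stays open. A difference in RNA integrity cannot be told apart from genotype, since the 3' over 5' ratio moved one way in all 3 depots for 2 of 3 control genes and each KO array is also the only one of its kind. The loss of Kdm4b, and differences in food intake or in the mice sampled, stay open as biological explanations that were not tested.

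Genotype differences common to the 3 depots exceeded the number expected if depots were independent. The labels do not say whether the 3 depots came from the same mice. If they did, any difference between those mice or in their handling would recur in all depots, and independence would not hold. The expected number also takes every gene as equally likely to differ, while genes with noisy signals would pass more often in every depot. Genes at least 2-fold different in opposite directions exceeded their expected number too, in each of the 3 pairs of depots. The excess therefore cannot tell genotype apart from differences between mice or from unequal noise of genes. Genes carried along with the Kdm4b locus from another strain were tested by the share of genes at least 1.5-fold different in all 3 depots, which within 10 Mb of Kdm4b was 1.82 times that elsewhere, but this rests on 1 gene of 105 (Trem1, named after its values were seen), against 63 of 12028 elsewhere, and within 5 Mb it was 0 of 51 genes, too few to decide. Blocks of another strain's DNA elsewhere were tested by pairs of the 64 genes within 2 Mb of each other. There were 5 such pairs, against a median of 6 in 10000 random sets, so close pairs were not in excess. A block holding a few of the genes would add few pairs to that background, and genes farther apart would add none. The count therefore cannot decide, and blocks with several such genes or a single one stay open. For the limma calls, the 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: limma called 0 genes in 10 of 10 splits, the real split included, and the highest of the others was 0. At an unadjusted p under 0.05 the real split gave 1102 genes and the highest other split 949, which divides the arrays of 1 depot only between its groups, while the other splits that divide all 3 depots, as the real one does, gave 659, 471 and 372.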

How the results depend on the processing

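No named gene past 2-fold and no list median outside random lists turned its sign under any alternative, while counts and their balance did shift. Under quantile normalization epididymal fat had 150 higher and 136 lower genes in place of 115 and 186, and under median centring brown against white fat had 3915 higher and 3186 lower in place of 2854 and 4109. The 2 alternatives that leave out muscle genes were chosen after seeing the data. With the floor at the 20th percentile, the genes at least 2-fold higher and lower numbered 524 and 627 in epididymal, 1297 and 322 in subcutaneous and 860 and 1141 in brown fat, and 23 and 9 in all 3 depots. With the floor at the 60th percentile they numbered 51 and 73, 69 and 47, and 42 and 72, with 3 higher in all depots. At 1.5-fold they numbered 578 and 860, 1207 and 518, and 664 and 1219, with 28 and 36 in all depots, and at 3-fold 11 and 40, 35 and 15, and 21 and 65, with 0 higher in all depots. Quantile normalization gave 197 higher genes in subcutaneous and 248 in brown fat. The mean of probe sets gave 102 lower genes in epididymal, 192 higher in subcutaneous, and 84 higher and 205 lower in brown fat, with 4 higher in all depots. The cause of the shifts with scaling and probe set rule was not tested. Of the 7 genes higher in all 3 depots, 6 were shared with the list after quantile normalization, 7 after median centring, 3 with the floor at the 60th percentile and 4 with the mean of probe sets. Quantile normalization lost Fdps, the higher floor Fbxw22, Ncan, Nppb and Tnfrsf12a, and the mean of probe sets Fdps, Ncan and Scyl2. Epididymal and subcutaneous fat alone shared 32 higher and 10 lower genes, epididymal and brown fat 11 and 16, and subcutaneous and brown fat 15 and 7.

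The genotype contrast of limma called 0 genes under every alternative and with each depot left out, except that the intensity trend called 19 higher and 14 lower. Brown against white fat kept its counts within 1.5 times except that 1824 higher genes were called without the brown WT array, with a range of 1824 to 2722 higher and 3061 to 3758 lower over the arrays left out. Subcutaneous against epididymal fat was the least stable contrast of the 3. Its higher and lower calls were 53 and 7 with the floor at the 20th percentile, 102 and 13 without a floor and 61 and 21 without a filter, while its lower calls were 255 after quantile normalization, 339 with the floor at the 60th percentile and 530 with the intensity trend. With arrays left out in turn, it called 64 to 463 higher and 10 to 114 lower genes, and the lone array left in a group was then assumed to vary like the others. It called 72 and 10 without the epididymal WT array, 64 and 13 without the epididymal KO array, 388 and 76 without the subcutaneous WT array and 302 and 111 without the subcutaneous KO array. Kdm4b in brown fat had a log2 difference of 0.00 with the floor at the 60th percentile, because both arrays were then at the floor. The correlation of genotype differences between epididymal and subcutaneous fat was 0.28 after quantile normalization, 0.15 with the floor at the 20th percentile and 0.34 at the 60th. Between epididymal and brown fat it was 0.15 at the 60th, and between subcutaneous and brown fat, 0.06 in the main analysis, it was -0.02 at the 20th and 0.17 at the 60th. Of the other values, 565 of 662 gene differences and 569 of 675 list medians under alternatives moved by less than their spread. Without the members that muscle also expresses, the thermogenic medians were -0.33, -0.14 and -0.13 in epididymal, subcutaneous and brown fat, and without the skeletal muscle list the genes at least 2-fold lower numbered 175, 100 and 311. The genotype fit with depot as a block pairs the WT and KO arrays of each depot, and within a depot there was nothing further to pair. Between 69.5% and 74.7% of genes lay above the floor on an array, and folds against the others are bounds.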

Other observations

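The genes named here were chosen after their values were seen, and no test of an explanation was run on them. All are among the genes at least 1.5-fold different in the same direction in all 3 depots. Hcar1, the lactate receptor gene of adipocytes, was lower by -1.11 in epididymal, -1.08 in subcutaneous and -0.99 in brown fat on the log2 scale, and Hcar2, the nicotinic acid and ketone body receptor gene, by -0.79, -1.28 and -0.85. Ptger3, a prostaglandin receptor gene, was higher by 0.80, 1.04 and 0.85. With an intensity trend, Hcar1 fell and Ptger3 rose in the limma fit (adjusted p = 0.0337 and 0.0225, each the same way in 3 of 3 depots), and without the trend the adjusted p of Hcar1 was 0.439. Hcar2 did not pass with the trend (limma adjusted p = 0.0795).

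Irf4, a transcription factor gene of fasting and thermogenesis in fat cells, was lower by -1.67, -0.83 and -0.72 in the 3 depots, and the glutamate transporter gene Slc1a3 by -1.37, -1.30 and -0.80. Cryab, a small heat shock protein gene, was higher by 0.94, 0.91 and 1.29. Slc1a3 and Cryab passed in the limma fit with an intensity trend (adjusted p = 0.0225 and 0.015, each the same way in 3 of 3 depots), and Irf4 did not (adjusted p = 0.123). Without the trend 0 of 13233 genes passed (smallest limma adjusted p = 0.439), so these calls, and that of Ptger3, rest on that setting alone. Cyp2f2 was lower by -2.60, -1.67 and -0.95. Of 10092 probe sets that gave no gene, controls left out, 0 were at least 2-fold higher and 3 at least 2-fold lower in all 3 KO arrays.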
